A study of Sus scrofa with 8 samples.

How the data were processed

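Tissue from Guizhou minipigs aged 8 months was sequenced as messenger RNA in 8 libraries, 2 each of native bladder mucosa, normal peritoneum, experimental neobladder mucosa and control neobladder mucosa. Per the labels, complementary DNA was made with Smart-seq2 and libraries with a TruSeq kit for an Illumina HiSeq X system. The deposited files hold raw counts per Ensembl gene, made by the authors with Trim Galore, HISAT2 and HTSeq 0.11.1 on the Sscrofa11.1 assembly, with settings and annotation release not stated. Values were checked to be whole numbers with library totals that differ. The 31907 genes of the files include 15029 with a symbol, and no library was left out.

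Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr over the 4 groups, which left 16549, of which 12436 had a symbol, and libraries were scaled by trimmed mean of M-values (TMM) factors. The factors were 0.839 and 0.449 in control neobladder and 1.088 to 1.239 in the other libraries. All groups entered 1 quasi-likelihood fit with robust spread (4 residual degrees of freedom, common dispersion 0.146, biological coefficient of variation 0.38), and the 6 pairwise comparisons were tested at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are given on the log2 scale. Levels are CPM on the TMM scale. On unscaled library totals, 3 counts in a library equal 0.252 to 0.378 CPM. TMM-scaled totals ran from 5.34 M counts in control neobladder replicate 2 to 13.38 M in native bladder replicate 2. On the TMM scale 3 counts therefore equal the most CPM in control neobladder replicate 2 and the fewest in native bladder replicate 2. Where both libraries of a group had 0 counts, the fold change is given as a bound against 3 counts over the group's 2 libraries, which covers counting error only.

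Gene lists, 30 in number, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They cover urothelium, mesothelium, enterocytes, intestinal identity, goblet cells, enteroendocrine cells, crypt stem cells, cell cycle, squamous differentiation, epithelial junctions, water, ion and urea transport, bile acid and xenobiotic handling, extracellular matrix, myofibroblasts, smooth muscle, skeletal muscle, adipocytes, endothelium, B cells, T and NK cells, macrophages, neutrophils, interferon response, antimicrobial defence, nerve and glia, hypoxia, immediate early genes, red blood cells, and nuclear and mitochondrially encoded oxidative phosphorylation. Each list with at least 4 tested members was tested for direction with fry, adjusted over the lists, beside counts of members called over all genes and over the list alone. More than 1 Ensembl gene carries the symbol GZMA, and each counts as a member of the T and NK cell list. Genes were named by rule: in the comparisons of experimental with control neobladder and of each neobladder with native bladder, the 8 largest log2 fold changes in each direction among called genes with a symbol, a mean of 5 CPM or more and no overlap between libraries, and the 4 largest in the other comparisons. For each list, up to 4 members with the smallest p and the member with the highest mean were also eligible. Not every eligible gene is described.

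The position of the experimental neobladder between 2 groups was a projection of log2 CPM (prior count 2), with different libraries on its 2 sides, over 8 combinations of libraries, a description with no test. Alternatives were DESeq2 1.42.0, its size factors, library totals alone, no low-count filter, the 2 groups alone, a test against a 1.5-fold change, replicate number as a block, each library left out in turn, and camera with a correlation of 0.01 or an estimated one. Repeat counts of list members in these settings and the third group's position were added after the data had been seen. The gene test, the list test and the position were tested on simulated data. With 200 genes changed in experimental neobladder, its test against control neobladder called 76, 6 of them wrongly. In the same simulated data, peritoneum against native bladder, where no gene was changed, gave 0 calls. A raised list gave adjusted p = 0.00942 by fry.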

Results

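The series measured messenger RNA by sequencing in 8 samples of tissue from Guizhou minipigs aged 8 months. A neobladder is a urinary reservoir built from a segment of ileum, and the study concerned lining it with the animal's own peritoneum in place of the ileal mucosa. The 4 groups held 2 libraries each: mucosa of the native bladder, normal peritoneum, mucosa of the experimental neobladder and mucosa of the control neobladder. The labels do not state how the control neobladder was lined, how long after surgery the mucosa was taken, or whether the replicates of a group came from separate animals. Every test therefore measured the spread between these samples only.

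Library totals, in M counts, ran from 7.94 M in peritoneum replicate 1 to 11.88 M in control neobladder replicate 2. The native bladder libraries held 10.68 and 11.03 M counts, the second peritoneum library 9.27 M, the experimental neobladder libraries 10.28 and 9.92 M, and control neobladder replicate 1 held 10.96 M. Between 17619 and 22761 genes had at least 1 count in a library. The 10 most abundant genes took 5.9 to 7.3% of the counts in the native bladder and experimental neobladder libraries, 14.8 and 16.4% in peritoneum, and 16.5 and 22.9% in the control neobladder. Replicates correlated across genes at r = 0.978 in native bladder, 0.956 in peritoneum, 0.974 in experimental neobladder and 0.909 in control neobladder, where genes are not independent replicates. Experimental neobladder and native bladder libraries correlated at 0.949 to 0.959, experimental and control neobladder at 0.713 to 0.786, and experimental neobladder and peritoneum at 0.730 to 0.740. Levels below are counts per M (CPM) scaled between libraries, as the mean of the 2 libraries of a group ± SD (n = 2). Adjusted p-values come from edgeR's quasi-likelihood test for genes and from fry for gene lists. Those given with an estimated correlation come from camera, a different test that compares a list with the other genes. List-adjusted counts are members called when p is adjusted over the list alone.

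The first comparison, of experimental with control neobladder mucosa, asked how the mucosa of a reservoir lined with peritoneum differed from that of a control reservoir. Urothelial and squamous genes were higher and intestinal genes lower in the experimental mucosa. UPK2, a uroplakin of the urothelial plaque, stood at 738 ± 571 CPM in experimental and 3.79 ± 2.59 CPM in control mucosa. FABP6, the bile acid binding protein of ileal enterocytes, stood at 29.6 ± 0.310 CPM against 94440 ± 89220 CPM. Of 16549 tested genes, 3584 differed, 1720 higher and 1864 lower in the experimental mucosa, each by over 2-fold.

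Of the 16 urothelium genes tested, 13 rose and 1 fell (13 and 1 list-adjusted), with a median log2 fold change of 6.53, or 5.46 with genes at 0 counts set to their bound. The list test by fry gave an adjusted p = 0.00177. Camera gave an adjusted p = 0.0543 with an estimated correlation and adjusted p = 8.81e-13 with a preset correlation of 0.01. KRT7, a keratin of simple and transitional epithelium, rose from 17.4 ± 13.3 to 2563 ± 519 CPM with a log2 fold change of 7.22. TP63, a transcription factor of basal epithelial cells, stood at 34.6 ± 2.95 against 0.109 ± 0.154 CPM, and SHH, a signal made by basal urothelium, at 29.1 ± 1.16 against 0.0937 ± 0.133 CPM, with 2 and 1 counts in the control libraries. Among squamous differentiation genes, 6 of 12 rose and none fell (6 and 0 list-adjusted, median log2 fold change 3.16, adjusted p = 0.00357, and adjusted p = 0.0853 with an estimated correlation). Involucrin (IVL), a cornified envelope precursor, rose from 13.4 ± 8.12 to 3312 ± 1775 CPM, its cross-linking enzyme TGM1 from 0.662 ± 0.141 to 45.5 ± 11.2 CPM, and KRT4, a keratin of stratified mucosa, from 2.88 ± 0.691 to 68.8 ± 21.6 CPM. The serine protease TMPRSS11E, at 214 ± 219 CPM and at 0 counts in the control libraries, was at least 1070-fold higher. CERS3, a ceramide synthase of epidermal barrier lipids, at 15.9 ± 3.39 CPM, and the ligand WNT7B, at 15.5 ± 6.87 CPM, were at least 76.3-fold and 74.2-fold higher by the same measure, which sets the group at 0 to 3 counts.

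Transport and junction genes went both ways. Of 25 water, ion and urea transport genes, 6 rose and 11 fell (8 and 11 list-adjusted), and of 23 junction genes 4 rose and 3 fell (5 and 3 list-adjusted). Neither list passed the test for 1 direction (adjusted p = 0.476, with a median log2 fold change of -0.99 and a mean of 0.20, and adjusted p = 0.203), while the test for either direction gave adjusted p = 0.000167 and adjusted p = 6.23e-05. The sodium channel subunit SCNN1B rose from 0.632 ± 0.431 to 117 ± 17.4 CPM, the urea transporter SLC14A1 from 0.381 ± 0.539 to 152 ± 14.5 CPM and the water channel AQP3 from 51.6 ± 5.98 to 427 ± 118 CPM. CA4, a membrane carbonic anhydrase, fell from 225 ± 38.4 to 5.06 ± 1.89 CPM. Claudin genes parted likewise: CLDN1 rose from 0.998 ± 0.179 to 143 ± 54.2 CPM and CLDN4 from 442 ± 222 to 3363 ± 1795 CPM, while the pore-forming CLDN2 stood at 0.131 ± 0.0543 against 121 ± 72.7 CPM, with 3 counts in the experimental libraries.

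**Figure D1:**
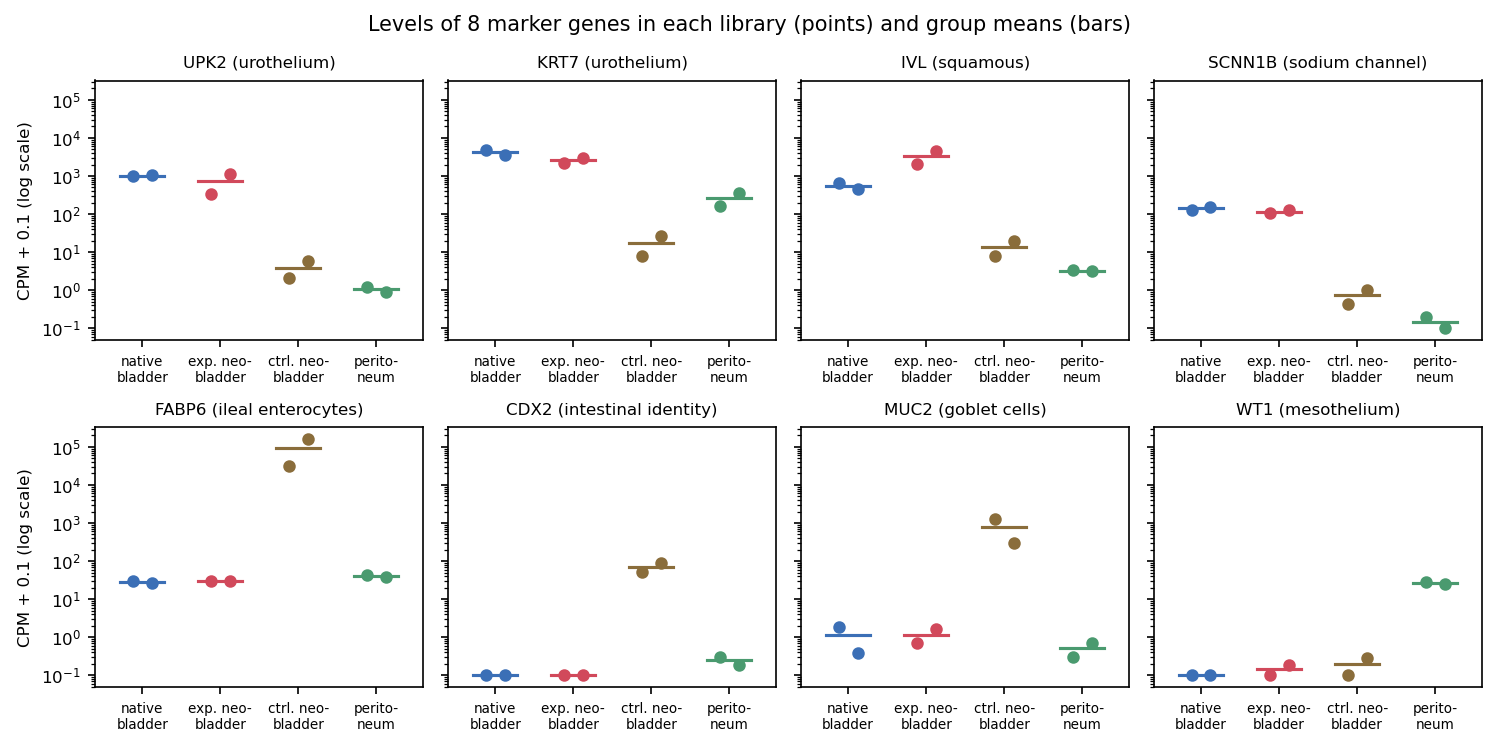
Levels of 8 marker genes, as CPM with 0.1 added on a log axis, in native bladder, experimental (exp.) and control (ctrl.) neobladder mucosa and peritoneum, with 1 point per library and a bar at the mean of 2. Both experimental libraries lie above both control libraries for UPK2, KRT7, IVL and SCNN1B and below them for FABP6, CDX2 and MUC2.

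All 24 tested enterocyte brush border and lipid handling genes fell (24 list-adjusted), with a median log2 fold change of -7.84 (adjusted p = 0.00139). SLC10A2, the ileal bile acid uptake transporter, fell from 577 ± 214 to 0.266 ± 0.0169 CPM, and the chylomicron apolipoprotein APOA4 stood at 0.0848 ± 0.120 against 268 ± 79.98 CPM, with 2 counts in the experimental libraries. Among genes of intestinal identity transcription factors and adhesion 9 of 14 fell and none rose (9 and 0 list-adjusted, median log2 fold change -3.73, adjusted p = 0.0037, adjusted p = 0.0853 with an estimated correlation, and adjusted p = 0.0544 on library totals alone). CDX2, the homeobox factor that sets intestinal identity, was at 0 counts in the experimental libraries against 69.1 ± 26.1 CPM, at least 483-fold lower. KRT20, a keratin of differentiated enterocytes, fell from 2716 ± 1208 to 1.25 ± 0.204 CPM, the nuclear receptor HNF4A from 191 ± 86.8 to 7.98 ± 0.256 CPM, and the galectin LGALS4 from 3816 ± 1249 to 753 ± 91.3 CPM. Of goblet and secretory genes 12 of 15 fell (14 lower and 1 higher list-adjusted, median log2 fold change -6.30, adjusted p = 0.00066), among them the mucin MUC2 from 768 ± 673 to 1.08 ± 0.695 CPM, the lectin REG4 from 6217 ± 5363 to 1.17 ± 0.740 CPM and the trefoil factor TFF2 from 871 ± 525 to 0.216 ± 0.174 CPM. Enteroendocrine genes fell in 8 of 11 cases (9 list-adjusted, median log2 fold change -8.34, or -7.30 with bounds, adjusted p = 0.00139). Proglucagon (GCG), at 471 ± 264 CPM in control mucosa, had 0 counts in the experimental libraries and was at least 3170-fold lower, and neurotensin (NTS) fell from 247 ± 209.5 to 0.177 ± 0.0113 CPM.

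All 21 cell cycle genes fell (21 list-adjusted, median log2 fold change -3.65, adjusted p = 0.00357, and adjusted p = 0.084 with an estimated correlation), with 12 called without experimental replicate 2. The mitotic kinase CDK1 fell from 103 ± 34.3 to 2.06 ± 2.12 CPM, cyclin B1 (CCNB1) from 95.98 ± 17.2 to 2.27 ± 0.983 CPM and thymidylate synthase (TYMS) from 61.2 ± 17.8 to 6.05 ± 0.885 CPM. Crypt stem and Wnt target genes went both ways, 4 higher and 5 lower of 15 (5 and 7 list-adjusted, adjusted p = 0.132). The crypt marker OLFM4 fell from 4554 ± 3096 to 0.879 ± 0.195 CPM, and the receptor TNFRSF19 rose from 3.05 ± 2.46 to 25.2 ± 1.98 CPM. Bile acid and xenobiotic genes fell as a list (5 of 8 lower and 1 higher, the same counts list-adjusted, median log2 fold change -4.90, adjusted p = 0.000363). The basolateral bile acid exporter SLC51B fell from 1378 ± 1121 to 1.01 ± 0.249 CPM, while CYP1A1, which oxidises aromatic hydrocarbons, rose from 655 ± 267 to 3344 ± 1019 CPM.

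Of 21 myofibroblast and scar genes, 12 rose and none fell (14 and 0 list-adjusted, median log2 fold change 1.90, adjusted p = 0.00277, and adjusted p = 0.084 with an estimated correlation), and of 15 smooth muscle genes 10 rose and none fell (12 and 0 list-adjusted, median 1.81, adjusted p = 0.000767). Smooth muscle actin (ACTA2) rose from 383 ± 79.5 to 2940 ± 229 CPM, the matricellular proteins CCN1 and CCN2 from 2.48 ± 1.12 to 143 ± 60.3 CPM and from 30.3 ± 13.2 to 889 ± 313 CPM, and smooth muscle myosin (MYH11) from 56.8 ± 13.8 to 395 ± 13.4 CPM. Genes of extracellular matrix and fibroblasts rose in 8 of 32 cases and fell in 1 (9 and 2 list-adjusted, median 0.94, adjusted p = 0.0234, and adjusted p = 0.34 with an estimated correlation). Thrombospondin 2 (THBS2) rose from 1.81 ± 0.0929 to 27.2 ± 13.7 CPM, while COL1A2, the list's most abundant member, stood at 1326 ± 25.1 against 512 ± 368 CPM (adjusted p = 0.156). Genes of endothelium and vessels rose in 5 of 18 cases and fell in none (6 and 0 list-adjusted, median 0.97, adjusted p = 0.0267, and adjusted p = 0.328 with an estimated correlation), TIE1 among them, from 1.66 ± 0.0374 to 9.41 ± 0.723 CPM. Mesothelium genes rose in 3 of 11 cases (3 list-adjusted, median 1.98, or 1.68 with bounds, adjusted p = 0.00164, and adjusted p = 0.188 with an estimated correlation). The members that rose were ALDH1A2, a retinoic acid synthesis enzyme, at 45.7 ± 6.12 against 0.865 ± 0.163 CPM, CDH3, a cadherin of basal epithelium, at 8.67 ± 0.201 against 0.632 ± 0.431 CPM, and HAS1, a hyaluronan synthase, at 4.71 ± 0.424 against 0.0544 ± 0.0770 CPM with 1 count in the control libraries. No member of the mesothelium list was called between experimental mucosa and native bladder. Against peritoneum 8 of the 11 were lower and 1 higher in experimental mucosa. Without experimental replicate 1 or 2 the endothelial list gave adjusted p = 0.101 and adjusted p = 0.111 and the matrix list adjusted p = 0.0793 and adjusted p = 0.0922. With replicate number as a block, endothelium and vessels gave adjusted p = 0.0537.

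Lists of interferon response, T and NK cell and macrophage genes were lower. Interferon response genes fell in 15 of 24 cases and rose in 1 (20 and 1 list-adjusted, median log2 fold change -2.20, adjusted p = 0.000363). The antiviral enzyme OAS1 fell from 90.6 ± 17.3 to 3.50 ± 0.0343 CPM and the guanylate-binding protein GBP1 from 603 ± 172 to 37.4 ± 4.01 CPM. Genes of T and NK cells fell in 12 of 21 cases and rose in none (12 and 0 list-adjusted, median -1.67, adjusted p = 0.0165, and adjusted p = 0.224 with an estimated correlation), with CD3D of the T cell receptor complex going from 131 ± 56.6 to 31.5 ± 10.7 CPM. Genes of macrophages and dendritic cells fell in 8 of 19 cases and rose in 1 (11 and 2 list-adjusted, median -1.56, adjusted p = 0.0262, and adjusted p = 0.328 with an estimated correlation), and the adaptor TYROBP fell from 652 ± 570.1 to 56.8 ± 12.9 CPM. On library totals alone the T cell and macrophage lists gave adjusted p = 0.0851 and adjusted p = 0.431, without experimental replicate 2 they gave adjusted p = 0.0874 and adjusted p = 0.132, and the macrophage list gave adjusted p = 0.065 without experimental replicate 1. B cell genes fell in 3 of 16 cases (3 list-adjusted, adjusted p = 0.109). Neutrophil and acute inflammation genes went both ways, 5 higher and 4 lower of 16 (6 and 4 list-adjusted, adjusted p = 0.445). Calgranulin C (S100A12) rose from 0.952 ± 1.04 to 114 ± 101 CPM, and interleukin 8 (CXCL8) fell from 352 ± 162 to 23.9 ± 18.5 CPM. Of 15 antimicrobial defence genes, 3 rose and 3 fell, the same counts list-adjusted (adjusted p = 0.697 in the higher direction, with a median of -0.07). Lipocalin 2 (LCN2) rose from 14.2 ± 9.60 to 2274 ± 649 CPM, the immunoglobulin carrier PIGR stood at 3647 ± 2212 against 2906 ± 2403 CPM (adjusted p = 0.768, and adjusted p = 0.0278 as higher without control replicate 1), and the bactericidal protein BPI stood at 0.135 ± 0.0712 against 546 ± 561 CPM.

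Among immediate early and heat shock genes, 10 of 18 rose and none fell (12 and 1 list-adjusted, median log2 fold change 1.90, adjusted p = 0.0165, and adjusted p = 0.328 with an estimated correlation), with FOS going from 95.2 ± 37.1 to 1148 ± 168 CPM. Without control replicate 1, control replicate 2 or experimental replicate 2 this list gave adjusted p = 0.0551, adjusted p = 0.0813 and adjusted p = 0.0501. In the list oxidative phosphorylation, nuclear, genes fell in 16 of 23 cases (20 list-adjusted, median -1.67, adjusted p = 0.042, and adjusted p = 0.34 with an estimated correlation), among them COX5B of cytochrome oxidase, from 4346 ± 4491 to 646 ± 50 CPM. Without experimental replicate 1 or 2, 0 of these genes were called and the list gave adjusted p = 0.142, and with replicate number as a block it gave adjusted p = 0.0599. The control libraries differed from each other with gene span (Spearman correlation -0.361), and the list's median was -2.17 without control replicate 1 and -1.06 without control replicate 2. Among adipocyte genes 4 of 13 fell, the same count list-adjusted (adjusted p = 0.109), among them lipoprotein lipase (LPL), from 136 ± 95.04 to 3.65 ± 0.482 CPM. The skeletal muscle list had 1 of 12 genes lower (adjusted p = 0.268, and adjusted p = 0.003 as higher on library totals alone), the nerve and glia list 1 of 9 lower (adjusted p = 0.342) and the hypoxia and glycolysis list 1 of 15 higher (adjusted p = 0.526), each with the same count list-adjusted. None of 4 red blood cell genes or 12 mitochondrially encoded genes was called by either adjustment (adjusted p = 0.935 and adjusted p = 0.776). The test for change in either direction passed every list of this comparison except B cells, red blood cells and mitochondrially encoded genes (adjusted p from 0.0589 to 0.644).

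Of the 30 lists, 18 passed, and 6 passed with an estimated correlation, these being the enterocyte, goblet, enteroendocrine, bile acid, smooth muscle and interferon lists. The balance of the calls rested on the scaling: 48% were higher in experimental mucosa as reported and 77.1% on library totals alone, where the median log2 fold change of all genes moved from 0.11 to 0.89. Without experimental replicate 1 or 2 the test called 1798 or 1292 genes, and without control replicate 1 it called 6424.

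**Figure D2:**
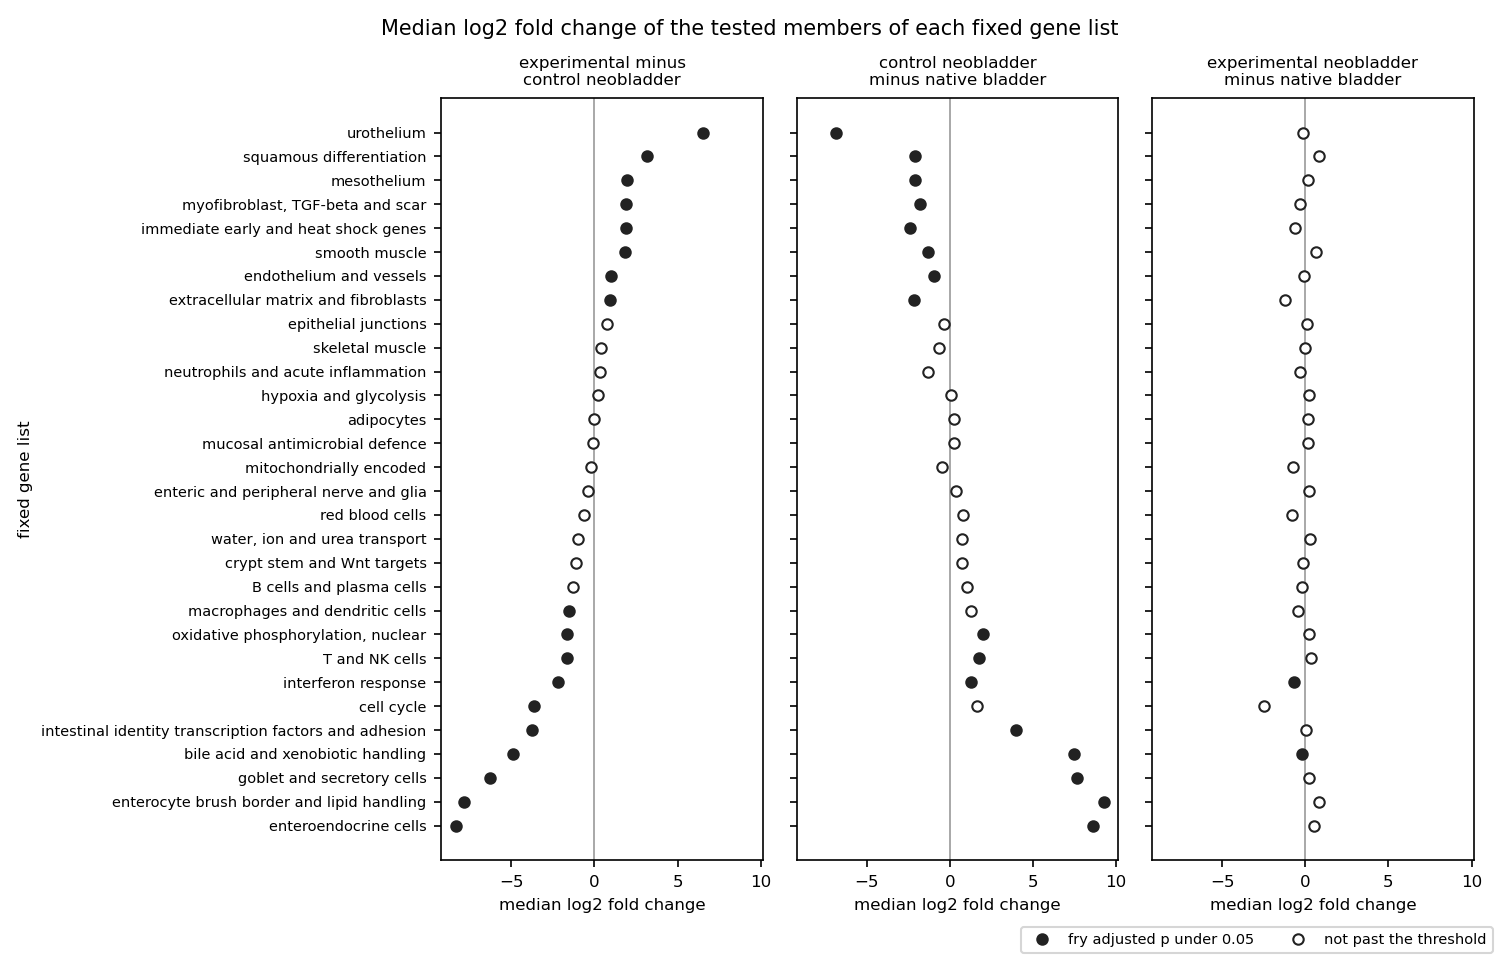
Median log2 fold change of the tested members of each of the 30 fixed gene lists in 3 comparisons, with filled points for lists past the fry threshold. For the urothelium list the medians were 6.53, -6.83 and -0.14 from left to right, and for the enterocyte list -7.84, 9.26 and 0.81.

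The comparison of experimental neobladder with native bladder asked how far the mucosa on the peritoneal lining resembled that of the organ it replaced. The test called 16 of 16549 genes, 7 higher and 9 lower in the experimental mucosa, with 1326 genes at an unadjusted p under 0.05. CYP1A1 stood at 3344 ± 1019 CPM in experimental mucosa and at 5.79 ± 1.53 CPM in native bladder, a log2 fold change of 9.17 (adjusted p = 0.00122). The related oxidase CYP1B1 rose from 21 ± 9.94 to 265 ± 143 CPM, and NR1I2, the pregnane X receptor that senses xenobiotics, from 0.861 ± 0.267 to 10.3 ± 1.85 CPM. MCM3, a subunit of the replicative helicase, fell from 68.7 ± 24.6 to 7.68 ± 0.639 CPM.

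Further genes that rose were KRT4, from 7.68 ± 1.36 to 68.8 ± 21.6 CPM, and MNDA, an interferon-inducible myeloid nuclear protein, from 1.64 ± 0.200 to 26.2 ± 11.6 CPM. The DNA glycosylase NEIL2 fell from 23.6 ± 5.23 to 1.40 ± 0.663 CPM and the repair and transcription helicase ERCC3 from 38.8 ± 1.54 to 6.55 ± 1.35 CPM. PLET1 fell from 26.8 ± 2.03 to 0.613 ± 0.212 CPM, BEX4 from 20.5 ± 4.31 to 0.617 ± 0.0861 CPM and FAM180A from 12.99 ± 5.16 to 0.926 ± 0.129 CPM. The other 5 genes had no symbol, 2 higher and 3 lower. Among these, chosen after their values were seen, were ENSSSCG00000005961, at 109 ± 59.2 against 0.152 ± 0.101 CPM, and ENSSSCG00000032135, at 0.0464 ± 0.0656 against 20.3 ± 5.51 CPM. The genes UPK2 (chromosome 9, 46200465 to 46202754), FABP6 (chromosome 16, 63297594 to 63303675), CYP1A1 (chromosome 7, 58802887 to 58809155), NR1I2 (chromosome 13, 140373571 to 140406129) and KRT4 (chromosome 5, 18091742 to 18099086) are placed on the pig assembly used for the counts.

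**Figure D3:**
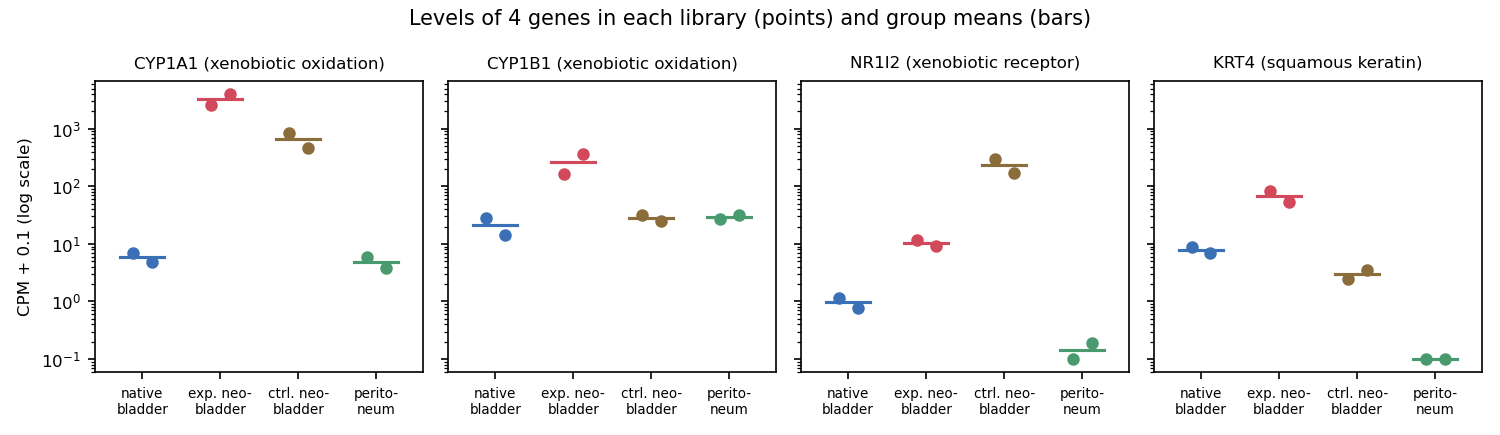
Levels of CYP1A1, CYP1B1, NR1I2 and KRT4, as CPM with 0.1 added on a log axis, with 1 point per library and a bar at the mean of 2, in native bladder, experimental (exp.) and control (ctrl.) neobladder mucosa and peritoneum. For each gene both experimental libraries lie above both native bladder libraries.

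No urothelium gene was called among 16 (none list-adjusted, median log2 fold change -0.14, adjusted p = 0.773). The uroplakin UPK1A stood at 28.8 ± 23.6 against 96.6 ± 8.61 CPM, KRT7 at 2563 ± 519 against 4195 ± 892 CPM and SHH at 29.1 ± 1.16 against 17.6 ± 0.0728 CPM. Squamous differentiation genes had 1 call of 12, KRT4 (3 list-adjusted, adjusted p = 0.0804), and IVL stood at 3312 ± 1775 against 542 ± 139.7 CPM. None of 24 enterocyte genes, 15 goblet genes, 11 enteroendocrine genes or 14 intestinal identity genes was called by either adjustment (adjusted p = 0.776, adjusted p = 0.771, adjusted p = 0.817 and adjusted p = 0.956), and LGALS4 stood at 753 ± 91.3 against 360.1 ± 54.7 CPM. The bile acid and xenobiotic list passed as higher with 2 of 8 called, CYP1A1 and NR1I2 (2 list-adjusted, adjusted p = 0.0255, and adjusted p = 0.11 with an estimated correlation), though its median log2 fold change was -0.21 and its mean 1.16. The interferon list passed as lower with 0 of 24 called (3 lower list-adjusted, median -0.67, adjusted p = 0.0255, and adjusted p = 0.109 with an estimated correlation), OAS1 standing at 3.50 ± 0.0343 against 9.10 ± 2.02 CPM.

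Cell cycle genes had 1 call of 21, MCM3 (16 lower list-adjusted, median log2 fold change -2.48), and the list did not pass (adjusted p = 0.0553). The helicase subunit MCM2 stood at 4.97 ± 2.44 against 50.8 ± 20.8 CPM and CCNB1 at 2.27 ± 0.983 against 15.3 ± 0.910 CPM. Extracellular matrix genes had none called of 32 (13 lower list-adjusted, median -1.22, adjusted p = 0.0523), with periostin (POSTN) at 38.7 ± 18.4 against 213 ± 30.6 CPM and COL1A2 at 1326 ± 25.1 against 4713 ± 88.8 CPM. Smooth muscle genes had none called of 15 (2 higher list-adjusted, median 0.65, adjusted p = 0.0523). The gelatinase MMP9 stood at 326 ± 181 against 33.8 ± 4.45 CPM (adjusted p = 0.0676) in the myofibroblast list, which had none called of 21 (1 higher list-adjusted, adjusted p = 0.981). T and NK cell genes had none called of 21 (4 higher and 1 lower list-adjusted, adjusted p = 0.776, and adjusted p = 1.05e-05 for change in either direction), with CD8B at 26.2 ± 5.98 against 2.49 ± 0.137 CPM. By the list-adjusted count, 1 mesothelium gene was higher, 1 junction gene, 1 skeletal muscle gene and 1 adipocyte gene lower, and 2 crypt genes and 2 neutrophil genes lower. The lists not named so far (water, B cell, macrophage, endothelial, antimicrobial, nerve, hypoxia, immediate early, red blood cell, nuclear and mitochondrial oxidative phosphorylation) had none called by either adjustment, and together with these 6 they gave adjusted p-values from 0.259 to 0.981. The test for change in either direction passed 13 of the 30 lists in this comparison. Besides T and NK cells these were bile acid (adjusted p = 0.000446), squamous (adjusted p = 0.00105), mesothelium (adjusted p = 0.00113), skeletal muscle (adjusted p = 0.00129), interferon (adjusted p = 0.00229), neutrophil (adjusted p = 0.00504), water transport (adjusted p = 0.0056) and crypt genes (adjusted p = 0.00717). The others were matrix, cell cycle and smooth muscle (each adjusted p = 0.0112) and myofibroblast genes (adjusted p = 0.0129).

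The bladder comparison depended on each library: CYP1A1 gave adjusted p = 0.0993 without native bladder replicate 1 and adjusted p = 0.0994 without native bladder replicate 2, the highest of its alternatives, which reached down to adjusted p = 2.65e-81 by DESeq2. Without any 1 of the 4 libraries 0 to 2 genes were called by edgeR. The list of bile acid and xenobiotic handling gave adjusted p-values from 0.074 to 0.177 without any 1 of them, and the interferon response list from 0.0657 to 0.0972 without native bladder replicate 2 or either experimental replicate. On library totals alone both lists gave adjusted p = 0.422, and with replicate number as a block both gave adjusted p = 0.0627. Other settings called more genes, 249 by DESeq2, 352 with no low-count filter and 542 in a fit of these 2 groups alone. Library totals alone gave 5. The reported fit shares 1 spread over all groups, including the control neobladder libraries, which correlated least as replicates (r = 0.909). In fits of 2 groups alone, calls rose in the comparisons without control neobladder (16 to 542, 3998 to 6103 and 3486 to 5735). They fell in those with it (3584 to 2456, 3686 to 2353 and 6993 to 4639), so the count of 16 depended on which groups entered the fit. Data were simulated with 200 changed genes among 16549, on the spread estimated from all 8 libraries, and experimental was tested against control neobladder. There the test recovered 0% of 2-fold, 29.9% of 4-fold and 75.8% of 8-fold changes. Recovery was not simulated for the bladder comparison itself, and genes not called here are not shown to be unchanged.

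Control neobladder against native bladder asked what mucosa the control reservoir carried. Intestinal genes were higher and urothelial genes lower in the control mucosa. FABP6 stood at 94440 ± 89220 CPM against 27.5 ± 2.29 CPM in native bladder, and UPK2 at 3.79 ± 2.59 against 1019 ± 45.1 CPM. Of the tested genes 3686 differed, 1857 higher and 1829 lower. BTNL2, a butyrophilin-like regulator of T cells, at 484 ± 329 CPM, and the cholesterol uptake transporter NPC1L1, at 152 ± 144 CPM, had 0 counts in native bladder and were at least 4690-fold and 1540-fold higher. TMPRSS11E and CLDN8, at 75.4 ± 3.53 and 25.4 ± 7.38 CPM in native bladder, had 0 counts in control mucosa and were at least 365-fold and 124-fold lower.

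All 24 enterocyte genes rose (24 list-adjusted, median log2 fold change 9.26, or 9.24 with bounds, adjusted p = 0.00167), with SLC10A2 at 577 ± 214 against 0.0374 ± 0.0528 CPM and 1 count in native bladder. Genes of intestinal identity transcription factors and adhesion rose in 9 of 14 cases (9 list-adjusted, median 4.0, adjusted p = 0.00359, adjusted p = 0.095 with an estimated correlation, and adjusted p = 0.0568 on library totals alone), and CDX2, at 0 counts in native bladder, was at least 551-fold higher. Goblet genes rose in 12 of 15 cases (14 higher and 1 lower list-adjusted, median 7.65, adjusted p = 0.00167). MUC2 went from 1.04 ± 1.04 to 768 ± 673 CPM. Enteroendocrine genes rose in 8 of 11 (10 list-adjusted, median 8.59, or 7.05 with bounds, adjusted p = 0.00167). NTS stood at 247 ± 209.5 against 0.121 ± 0.171 CPM, with 3 counts in native bladder. Bile acid and xenobiotic genes rose in 6 of 8 cases, the same count list-adjusted (median 7.44, adjusted p = 0.000281), with NR1I2 going from 0.861 ± 0.267 to 233 ± 91.1 CPM and CYP1A1 from 5.79 ± 1.53 to 655 ± 267 CPM.

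Urothelium genes fell in 13 of 16 cases (13 list-adjusted, median log2 fold change -6.83, or -5.70 with bounds, adjusted p = 0.00142). KRT7 went from 4195 ± 892 to 17.4 ± 13.3 CPM. Squamous genes fell in 6 of 12 cases and rose in 1 (6 and 1 list-adjusted, median -2.12, adjusted p = 0.0168, and adjusted p = 0.283 with an estimated correlation). IVL went from 542 ± 139.7 to 13.4 ± 8.12 CPM. Extracellular matrix genes fell in 23 of 32 cases (27 lower and 1 higher list-adjusted, median -2.15, adjusted p = 0.00167, and adjusted p = 0.095 with an estimated correlation). COL1A2 went from 4713 ± 88.8 to 512 ± 368 CPM. Myofibroblast genes fell in 11 of 21 (16 list-adjusted, median -1.78, adjusted p = 0.00337, and adjusted p = 0.0961 with an estimated correlation). Smooth muscle genes fell in 4 of 15 (7 list-adjusted, median -1.33, adjusted p = 0.00167, and adjusted p = 0.0961 with an estimated correlation). Endothelial genes fell in 5 of 18 (6 list-adjusted, median -0.98, adjusted p = 0.0281, and adjusted p = 0.351 with an estimated correlation). ACTA2 fell from 2896 ± 226 to 383 ± 79.5 CPM. The mesothelium list passed as lower with 4 lower and 2 higher of 11 (5 and 2 list-adjusted, median -2.08, adjusted p = 0.0026, and adjusted p = 0.283 with an estimated correlation), ALDH1A2 going from 32.9 ± 2.19 to 0.865 ± 0.163 CPM. Immediate early genes fell in 12 of 18 cases (13 lower and 1 higher list-adjusted, median -2.39, adjusted p = 0.00747, and adjusted p = 0.244 with an estimated correlation). FOS went from 1806 ± 327 to 95.2 ± 37.1 CPM.

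Among interferon response genes, 12 of 24 rose and 1 fell (13 and 1 list-adjusted, median log2 fold change 1.27, adjusted p = 0.000281, and adjusted p = 0.23 on library totals alone). GBP1 went from 59.97 ± 9.76 to 603 ± 172 CPM. Genes of T and NK cells rose in 11 of 21 (13 list-adjusted, median 1.77, adjusted p = 0.0131, adjusted p = 0.211 with an estimated correlation, and adjusted p = 0.0736 on library totals alone). The chemokine CCL5 went from 20.2 ± 1.52 to 203 ± 142 CPM. Nuclear oxidative phosphorylation genes rose in 20 of 23 (20 list-adjusted, median 1.97, adjusted p = 0.0321, and adjusted p = 0.307 with an estimated correlation). COX5B went from 465 ± 132 to 4346 ± 4491 CPM. The other 14 lists did not pass (adjusted p from 0.0882 to 0.786). Members called in these were 5 higher and 3 lower of crypt, 9 higher of cell cycle, 3 higher and 3 lower of junction, 8 higher and 4 lower of water transport, 1 higher and 1 lower of skeletal muscle, and 4 higher of adipocyte genes. They were also 4 higher of B cell, 6 higher and 4 lower of macrophage, 3 higher and 6 lower of neutrophil, 5 higher and 3 lower of antimicrobial, 1 lower of nerve, 1 higher of hypoxia, 0 of red blood cell and 1 higher of mitochondrially encoded genes. By the list-adjusted count, the counts that differed were 11 higher of cell cycle, 7 lower of water transport, 10 higher of macrophage, 7 lower of neutrophil and 0 of mitochondrially encoded genes.

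Calls higher in control mucosa made up 50.4% as reported and 18.7% on library totals alone, where the median log2 fold change of all genes moved from -0.11 to -0.97. Without native bladder replicate 1 or 2 the test called 1347 or 1569 genes, and without control replicate 1 it called 6512. List calls that ended without 1 library were T and NK cells (adjusted p = 0.0703 and adjusted p = 0.0768), endothelium and vessels (adjusted p = 0.118 and adjusted p = 0.129) and oxidative phosphorylation, nuclear (adjusted p = 0.137 and adjusted p = 0.124, with 0 genes called) without native bladder replicate 1 or 2. Further ones were squamous differentiation without control replicate 1 or 2 (adjusted p = 0.0796 and adjusted p = 0.0638) and immediate early and heat shock genes without control replicate 2 (adjusted p = 0.0554). With replicate number as a block the endothelial and the nuclear oxidative phosphorylation list both gave adjusted p = 0.0522. The control libraries differed from each other with gene span (Spearman correlation -0.361), and the median of the latter list was 2.33 without control replicate 1 and 1.35 without control replicate 2.

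The experimental neobladder was set against peritoneum to ask how the mucosa differed from the tissue used to line the reservoir. Urothelial and epithelial genes were higher, and mesothelial, matrix and fat genes lower, in the experimental mucosa. UPK2 stood at 738 ± 571 against 0.961 ± 0.225 CPM, and WT1 (chromosome 2, 28411467 to 28456007), the transcription factor of mesothelium, at 0.0464 ± 0.0656 against 26.5 ± 1.70 CPM, with 1 count in the experimental libraries. The test called 3998 genes, 2044 higher and 1954 lower. KRT4, at 68.8 ± 21.6 CPM and 0 counts in peritoneum, was at least 488-fold higher. EPYC, a small leucine-rich proteoglycan, at 87.01 ± 14.6 CPM in peritoneum, and the homeobox gene HOXC8, at 26.99 ± 1.15 CPM, had 0 counts in experimental mucosa and were at least 660.0-fold and 204-fold lower.

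Urothelium genes rose in 14 of 16 cases (14 list-adjusted, median log2 fold change 7.71, or 7.65 with bounds, adjusted p = 0.00192, and adjusted p = 0.0976 with an estimated correlation). Squamous genes rose in 10 of 12 (11 list-adjusted, median 5.09, or 3.77 with bounds, adjusted p = 0.00192, and adjusted p = 0.0976 with an estimated correlation). IVL went from 3.15 ± 0.163 to 3312 ± 1775 CPM. Junction genes rose in 13 and fell in 3 of 23 (16 and 4 list-adjusted, adjusted p = 0.00794, and adjusted p = 0.162 with an estimated correlation). CLDN7 went from 3.50 ± 0.341 to 1140 ± 255 CPM. Water transport genes rose in 10 of 25 (10 higher and 1 lower list-adjusted, adjusted p = 0.00517, and adjusted p = 0.162 with an estimated correlation). AQP3 went from 13.7 ± 9.16 to 427 ± 118 CPM. Genes of intestinal identity transcription factors and adhesion rose in 9 and fell in 1 of 14, the same counts list-adjusted. Their median was 4.07, or 3.32 with bounds (adjusted p = 0.00377, and adjusted p = 0.113 with an estimated correlation). Among those called were TMEM45B, from 0.331 ± 0.0359 to 234 ± 46.7 CPM, the epithelial adhesion molecule EPCAM, from 2.32 ± 0.117 to 477 ± 65.5 CPM, and LGALS4, from 1.39 ± 0.810 to 753 ± 91.3 CPM. CDX2 had 0 counts in the experimental libraries, and 9 genes of this list were also higher in native bladder than in peritoneum, with 1 lower. Goblet genes rose in 5 of 15 (6 list-adjusted, adjusted p = 0.0184, and adjusted p = 0.172 with an estimated correlation). Bile acid and xenobiotic genes rose in 4 of 8 (5 list-adjusted, adjusted p = 0.000968, and adjusted p = 0.102 with an estimated correlation). CYP1A1 went from 4.73 ± 1.52 to 3344 ± 1019 CPM.

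Mesothelium genes fell in 8 of 11 cases and rose in 1 (8 and 2 list-adjusted, median log2 fold change -4.03, adjusted p = 0.000367, and adjusted p = 0.0976 with an estimated correlation). GPM6A, a membrane glycoprotein of mesothelium, fell from 185 ± 13.8 to 3.90 ± 0.122 CPM, and the 1 that rose was the epithelial keratin KRT18, from 2.29 ± 1.09 to 138 ± 60.6 CPM. Extracellular matrix genes fell in 28 of 32 (29 list-adjusted, median -3.27, adjusted p = 0.00192, and adjusted p = 0.0976 with an estimated correlation). Elastin (ELN) went from 106 ± 49.04 to 1.73 ± 0.0784 CPM and COL1A2 from 19530 ± 1415 to 1326 ± 25.1 CPM. Adipocyte genes fell in 9 and rose in 1 of 13, the same counts list-adjusted (median -4.47, adjusted p = 0.00392, and adjusted p = 0.154 with an estimated correlation). Adiponectin (ADIPOQ) went from 499.5 ± 167 to 0.466 ± 0.659 CPM. Endothelial genes fell in 11 of 18 (14 list-adjusted, median -1.61, adjusted p = 0.00937, and adjusted p = 0.162 with an estimated correlation). PECAM1 went from 1287 ± 282 to 267 ± 38.5 CPM. Smooth muscle genes rose in 7 and fell in 1 of 15 (8 and 1 list-adjusted, adjusted p = 0.00292, and adjusted p = 0.102 with an estimated correlation). The nerve list passed as lower with 3 lower and 2 higher of 9 (5 and 2 list-adjusted, adjusted p = 0.00392, and adjusted p = 0.172 with an estimated correlation).

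Lists of lymphocytes and neutrophils were higher in experimental mucosa. B cell and plasma cell genes rose in 11 of 16 cases (14 list-adjusted, adjusted p = 0.0086, and adjusted p = 0.162 with an estimated correlation). The immunoglobulin joining chain (JCHAIN) went from 12.8 ± 3.03 to 1395 ± 895 CPM. T and NK cell genes rose in 9 of 21 (10 list-adjusted, adjusted p = 0.00813, and adjusted p = 0.172 with an estimated correlation). CD8A went from 5.89 ± 2.13 to 50.9 ± 14.3 CPM. Neutrophil genes rose in 7 of 16 (10 list-adjusted, adjusted p = 0.00392, and adjusted p = 0.113 with an estimated correlation). CXCL8 went from 0.586 ± 0.684 to 23.9 ± 18.5 CPM. Antimicrobial genes rose in 6 and fell in 2 of 15 (7 and 2 list-adjusted, adjusted p = 0.0184, and adjusted p = 0.184 with an estimated correlation). PIGR went from 4.12 ± 0.350 to 3647 ± 2212 CPM. Interferon genes fell in 8 and rose in 1 of 24 (9 and 1 list-adjusted, adjusted p = 0.00377, and adjusted p = 0.162 with an estimated correlation). Immediate early genes rose in 11 of 18 (13 list-adjusted, adjusted p = 0.00669, and adjusted p = 0.166 with an estimated correlation), and the hypoxia list passed as higher with 4 higher and 1 lower of 15 (6 and 2 list-adjusted, adjusted p = 0.0382, and adjusted p = 0.28 with an estimated correlation). The other 10 lists did not pass (adjusted p from 0.0585 to 0.969). Their calls were 4 higher and 1 lower of enterocyte, 3 and 5 of crypt, 0 and 1 of cell cycle, 6 and 6 of myofibroblast, 2 and 1 of skeletal muscle, 0 and 3 of macrophage, and 6 and 0 of nuclear oxidative phosphorylation genes, with 0 of enteroendocrine, red blood cell and mitochondrially encoded genes. By the list-adjusted count these became 5 and 2 of enterocyte, 4 and 5 of crypt, 0 and 0 of cell cycle, 8 and 7 of myofibroblast, and 3 and 1 of skeletal muscle genes.

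Without 1 library the test called between 1709 genes (without experimental replicate 2) and 2397 (without peritoneum replicate 2), with 2090 without experimental replicate 1 and 2273 without peritoneum replicate 1, and 6103 in a fit of these 2 groups alone. List calls that ended in at least 1 such fit were B cells and plasma cells (adjusted p = 0.0579) and T and NK cells (adjusted p = 0.056) without peritoneum replicate 1, immediate early and heat shock genes (adjusted p = 0.0525) without peritoneum replicate 2, and the lists of epithelial junctions, goblet and secretory cells, and mucosal antimicrobial defence without either (adjusted p from 0.0585 to 0.123). The lists of endothelium and vessels and of hypoxia and glycolysis ended without any 1 of the 4 libraries (adjusted p from 0.0553 to 0.238), and on library totals alone these, the junction, interferon and antimicrobial lists gave adjusted p from 0.0538 to 0.33.

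Control neobladder against peritoneum was made as the reference for the preceding comparison. It gave 6993 calls, 3577 higher and 3416 lower in control mucosa. FABP6 stood at 94440 ± 89220 against 41.4 ± 3.17 CPM and ALDH1A2 at 0.865 ± 0.163 against 134 ± 7.09 CPM. BTNL2, at 0 counts in peritoneum, was at least 3830-fold higher, and EPYC, at 0 counts in control mucosa, at least 424-fold lower.

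Enterocyte genes rose in all 24 cases (24 list-adjusted, median log2 fold change 9.87, or 9.52 with bounds, adjusted p = 0.00133, and adjusted p = 0.0562 with an estimated correlation). Identity genes rose in 13 of 14 (13 list-adjusted, median 9.98, or 9.36 with bounds, adjusted p = 0.000929, and adjusted p = 0.0528 with an estimated correlation). Goblet genes rose in all 15 (15 list-adjusted, median 10.24, or 9.46 with bounds, adjusted p = 0.000849, and adjusted p = 0.0528 with an estimated correlation). Enteroendocrine genes rose in 9 of 11 (9 list-adjusted, adjusted p = 0.00109, and adjusted p = 0.0562 with an estimated correlation). Bile acid genes rose in all 8 (8 list-adjusted, adjusted p = 0.000183, and adjusted p = 0.0528 with an estimated correlation). Cell cycle genes rose in all 21 (21 list-adjusted, adjusted p = 0.00585, and adjusted p = 0.188 with an estimated correlation). HNF4A stood at 191 ± 86.8 CPM against 0 counts, at least 1450-fold higher, and CCNB1 rose from 2.58 ± 2.26 to 95.98 ± 17.2 CPM. Nuclear oxidative phosphorylation genes rose in 22 of 23 (23 list-adjusted, adjusted p = 0.0102, and adjusted p = 0.25 with an estimated correlation). Water transport genes rose in 16 of 25 (16 higher and 1 lower list-adjusted, adjusted p = 0.00401, and adjusted p = 0.183 with an estimated correlation). Junction genes rose in 14 with 4 lower of 23, the same counts list-adjusted (adjusted p = 0.0255, and adjusted p = 0.366 with an estimated correlation). Squamous genes rose in 7 with 2 lower of 12, the same counts list-adjusted (adjusted p = 0.024, and adjusted p = 0.376 with an estimated correlation).

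Genes of mesothelium fell in 9 of 11 cases and rose in 1 (10 and 1 list-adjusted, adjusted p = 0.000183, and adjusted p = 0.0528 with an estimated correlation). Matrix genes fell in 27 of 32 and rose in 1, the same counts list-adjusted (adjusted p = 0.000183, and adjusted p = 0.0528 with an estimated correlation). Endothelial genes fell in 14 of 18 (15 list-adjusted, adjusted p = 0.00109, and adjusted p = 0.0969 with an estimated correlation). Adipocyte genes fell in 7 and rose in 2 of 13 (adjusted p = 0.0125, and adjusted p = 0.314 with an estimated correlation). Myofibroblast genes fell in 10 and rose in 3 of 21 (adjusted p = 0.00604, and adjusted p = 0.235 with an estimated correlation). Nerve genes fell in 3 and rose in 2 of 9 (adjusted p = 0.00585, and adjusted p = 0.376 with an estimated correlation), and these 3 lists had the same counts list-adjusted. COL1A2 fell from 19530 ± 1415 to 512 ± 368 CPM and ADIPOQ from 499.5 ± 167 to 0.850 ± 0.123 CPM. B cell genes rose in 14 of 16 (14 list-adjusted, adjusted p = 0.0037, and adjusted p = 0.129 with an estimated correlation). T and NK cell genes rose in 18 of 21 (19 list-adjusted, adjusted p = 0.00133, and adjusted p = 0.0969 with an estimated correlation). Neutrophil genes rose in 10 of 16 (10 list-adjusted, adjusted p = 0.00581, and adjusted p = 0.202 with an estimated correlation). Interferon genes rose in 11 and fell in 1 of 24 (adjusted p = 0.000849, and adjusted p = 0.0969 with an estimated correlation). Antimicrobial genes rose in 6 and fell in 2 of 15 (adjusted p = 0.0255, and adjusted p = 0.359 with an estimated correlation), and both lists had the same counts list-adjusted. The other 9 lists did not pass (adjusted p from 0.0695 to 0.722), with 4 higher and 3 lower of urothelium, 5 and 5 of crypt, 2 and 3 of smooth muscle, 3 and 2 of skeletal muscle, 9 and 3 of macrophage, 3 and 1 of hypoxia, 4 and 0 of immediate early, 0 of red blood cell and 2 and 0 of mitochondrially encoded genes. By the list-adjusted count, 7 crypt and 11 macrophage genes were higher and 0 mitochondrially encoded genes, the rest being as given.

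On library totals alone 24.9% of calls were higher against 51.2% as reported, the median log2 fold change of all genes moved from -0.06 to -0.96, and mucosal antimicrobial defence turned lower (adjusted p = 0.927). In that fit the lists of water, ion and urea transport, squamous differentiation, interferon response and epithelial junctions gave adjusted p from 0.0924 to 0.419. List calls that ended without peritoneum replicate 1 or 2 were junction, antimicrobial and squamous (adjusted p from 0.122 to 0.176), and without peritoneum replicate 1 oxidative phosphorylation, nuclear (adjusted p = 0.0531) and neutrophils and acute inflammation (adjusted p = 0.05). Without control replicate 1 adipocytes (adjusted p = 0.0689) and squamous differentiation (adjusted p = 0.0606) lost their call, as did the squamous list without control replicate 2 (adjusted p = 0.0707) and with replicate number as a block (adjusted p = 0.0571).

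Peritoneum against native bladder gave the difference between the lining tissue and the organ it was to stand in for. Peritoneum was higher in mesothelial, matrix, fat and vessel genes and lower in urothelial, epithelial, lymphocyte and neutrophil genes. WT1, at 26.5 ± 1.70 CPM and 0 counts in native bladder, was at least 227-fold higher, and UPK1A, at 96.6 ± 8.61 CPM and 0 counts in peritoneum, at least 679-fold lower. The test called 3486 genes, 1644 higher and 1842 lower.

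Mesothelium genes rose in 7 of 11 cases and fell in 1 (8 and 1 list-adjusted, median log2 fold change 2.76, adjusted p = 0.000346, and adjusted p = 0.144 with an estimated correlation), the Wnt agonist RSPO1 from 0.159 ± 0.118 to 44.5 ± 21.1 CPM. Extracellular matrix genes rose in 21 and fell in 1 of 32 (25 and 1 list-adjusted, adjusted p = 0.0054, and adjusted p = 0.154 with an estimated correlation). Decorin (DCN) went from 479 ± 38.4 to 11580 ± 3693 CPM. Adipocyte genes rose in 9 of 13 (9 higher and 1 lower list-adjusted, adjusted p = 0.00631, and adjusted p = 0.16 with an estimated correlation). ADIPOQ went from 0.824 ± 0.320 to 499.5 ± 167 CPM. Endothelial genes rose in 10 of 18 (13 list-adjusted, adjusted p = 0.0098, and adjusted p = 0.182 with an estimated correlation). Nerve genes rose in 4 and fell in 2 of 9, the same counts list-adjusted (adjusted p = 0.00641, and adjusted p = 0.19 with an estimated correlation). LGR5, a Wnt-regulated receptor, rose from 0.460 ± 0.194 to 204 ± 121 CPM.

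Urothelium genes fell in 13 of 16 cases (15 list-adjusted, adjusted p = 0.00174, and adjusted p = 0.122 with an estimated correlation). Squamous genes fell in 7 of 12 (10 list-adjusted, adjusted p = 0.00569, and adjusted p = 0.154 with an estimated correlation). Junction genes fell in 11 with 2 higher of 23 (14 and 3 list-adjusted, adjusted p = 0.00938, and adjusted p = 0.182 with an estimated correlation). Water transport genes fell in 12 and rose in 1 of 25 (12 and 2 list-adjusted, adjusted p = 0.00631, and adjusted p = 0.182 with an estimated correlation). Identity and adhesion genes fell in 9 and rose in 1 of 14, the same counts list-adjusted (adjusted p = 0.0054, and adjusted p = 0.154 with an estimated correlation). Goblet genes fell in 4 of 15, the same count list-adjusted (adjusted p = 0.0247, and adjusted p = 0.228 with an estimated correlation). Bile acid genes fell in 3 of 8 (4 list-adjusted, adjusted p = 0.0047, and adjusted p = 0.182 with an estimated correlation). Cell cycle genes fell in 10 of 21 (15 list-adjusted, adjusted p = 0.0247, and adjusted p = 0.238 with an estimated correlation). Smooth muscle genes fell in 3 of 15, the same count list-adjusted (adjusted p = 0.00866, and adjusted p = 0.19 with an estimated correlation). CLDN4 fell from 3764 ± 2465 to 10.7 ± 2.89 CPM and the enteric smooth muscle actin ACTG2 from 555 ± 183 to 3.98 ± 4.19 CPM. B cell genes fell in 12 of 16, the same count list-adjusted (adjusted p = 0.00693, and adjusted p = 0.169 with an estimated correlation). T and NK cell genes fell in 10 of 21 (11 list-adjusted, adjusted p = 0.00938, and adjusted p = 0.214 with an estimated correlation). Neutrophil genes fell in 10 of 16 (13 list-adjusted, adjusted p = 0.0054, and adjusted p = 0.154 with an estimated correlation). Immediate early genes fell in 13 of 18 (16 list-adjusted, adjusted p = 0.00569, and adjusted p = 0.169 with an estimated correlation). Antimicrobial genes fell in 4 and rose in 2 of 15, the same counts list-adjusted (adjusted p = 0.0216, and adjusted p = 0.226 with an estimated correlation). The other 11 lists did not pass (adjusted p from 0.119 to 0.948), with 1 higher and 2 lower of enterocyte, 1 and 0 of enteroendocrine, 4 and 5 of crypt, 5 and 6 of myofibroblast, 0 and 3 of skeletal muscle, 2 and 1 of macrophage, 2 and 3 of interferon, 1 and 1 of hypoxia and 0 and 3 of oxidative phosphorylation genes, and 0 of red blood cell and mitochondrially encoded genes. By the list-adjusted count these were the same except 0 enteroendocrine and 1 macrophage gene higher, 5 crypt genes higher and 6 lower, and 4 interferon, 4 hypoxia and 0 oxidative phosphorylation genes lower.

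Leaving out native bladder replicate 1 or 2 gave 1297 or 1583 calls, leaving out peritoneum replicate 1 or 2 gave 1874 or 2014, and a fit of these 2 groups alone 5735. The lists of cell cycle, endothelium and vessels, goblet and secretory cells, and mucosal antimicrobial defence lost their call without any 1 of these libraries (adjusted p from 0.0564 to 0.149). Others ended without either peritoneum replicate, epithelial junctions (adjusted p = 0.0701 and adjusted p = 0.068), without peritoneum replicate 1, B cells and plasma cells, T and NK cells and water, ion and urea transport (adjusted p from 0.0541 to 0.0564), smooth muscle without peritoneum replicate 2 (adjusted p = 0.0568) and enteric and peripheral nerve and glia without native bladder replicate 2 (adjusted p = 0.054). On library totals alone 11 of the 30 lists passed in place of 19, and with replicate number as a block the goblet list gave adjusted p = 0.0552.

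Placed by all 16549 genes on the line from control neobladder (0) to native bladder (1), the experimental neobladder lay at 0.931, with its libraries at 0.899 and 0.963. Peritoneum itself lay at 0.867 on that line. On the line from control neobladder (0) to peritoneum (1) the experimental neobladder lay at 0.488, with its libraries at 0.478 and 0.499, and native bladder itself at 0.518. Both reference positions were added after the data had been seen. In data simulated at 0, 0.5 and 1 between the mean log2 levels of control neobladder and native bladder, the method returned 0.001, 0.508 and 0.997. Mixtures of tissues were not simulated, so a position is not a mixing fraction.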

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

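The 14 results were recomputed with 1 choice changed at a time, except that DESeq2 changes scaling and test together, all chosen before the data were examined, and the cause of the shifts was not tested. Where a library is left out, the lone library of its group is assumed to vary like the others. For experimental against control neobladder, 1292 to 6424 genes were called in leave-one-out fits against 3584, and 6 lists passed against 18 with an estimated correlation. For experimental neobladder against native bladder, where 16 genes were called, the count was 5 on library totals alone, 352 with no low-count filter, 542 in the 2 groups alone, 10 against a 1.5-fold change, 249 by DESeq2, 16 by edgeR with the size factors of DESeq2 and 0 to 2 in leave-one-out fits. Its 2 lists became 0 on library totals alone and 0 with the replicate block. Camera passed 8 lists with a preset correlation and 0 with an estimated one. Such counts cover all lists passing in a setting, not only those of the reported fit. The bile acid list lost its call in every leave-one-out fit of this comparison. For control neobladder against native bladder, 2353 genes were called in the 2 groups alone and 1347 to 6512 in leave-one-out fits against 3686, with 6 lists against 16 with an estimated correlation. For experimental neobladder against peritoneum, 6103 genes were called in the 2 groups alone and 1709 to 2397 in leave-one-out fits against 3998, with 0 lists with an estimated correlation and 13 to 18 in leave-one-out fits against 20. For control neobladder against peritoneum, 4639 genes were called in the 2 groups alone against 6993, and 0 lists passed with an estimated correlation against 21. For peritoneum against native bladder, 5735 genes were called in the 2 groups alone and 1297 to 2014 in leave-one-out fits against 3486, with 11 lists on library totals alone, 0 with an estimated correlation and 11 to 15 in leave-one-out fits against 19. With the replicate block the gene counts were 3140, 14, 3268, 3657, 6400 and 3163 in the order of the report, and correlations between replicate differences of 2 groups ran from -0.115 to 0.138. The position toward peritoneum was 0.504 on library totals alone against 0.488. Among named genes, 1424 comparisons with an alternative kept their direction and side of the threshold, 88 lost the call, 26 gained one and 2 reversed. The reversals were PIGR in experimental against control neobladder, not called in the reported fit at a log2 fold change of 0.33, which became -0.48 without experimental replicate 1 and -0.41 without control replicate 2, and 1.60 without control replicate 1.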

Other observations

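The tests of the 3 patterns below and their predictions were chosen after the results they concern had been seen.

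The first pattern was the closeness of experimental neobladder to native bladder. The 46 genes restricted to peritoneum stood at a median of 0.714% of their peritoneum level (quartiles 0.272 and 1.88%, and medians of 0.984 and 0.29% in experimental replicates 1 and 2), which argues against peritoneal tissue with its own profile making up the samples. A first test of whether both hold the same material, genes at 10 CPM or more in 1 library and under 0.1 of that in the other, gave 14 to 44 genes between groups and 0 to 12 between replicates and decided nothing. A second was chosen after the first and the 16 calls of the report had been seen. It counted genes whose bladder and experimental libraries lie at least 4-fold apart. These were 58, against 0 and 0 in the other splits of these 4 libraries. Those calls had already shown genes apart, and any count over 0 would have met its bound, so the test was not independent. The 58 genes show that the groups' libraries differed. Bladder mucosa from other animals could also differ so, and no conclusion is drawn on the same material. The 32 genes restricted to bladder stood at a median of 83% of their bladder level (quartiles 51.5 and 131%), so native bladder mucosa in the samples cannot be told apart from urothelium grown over the lining, since both would give these levels.

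The second pattern was the high CYP1A1 and CYP1B1 of experimental neobladder, at 511 and 934% of their control neobladder level. A share of control mucosa at its own level could not lift a gene above that level, so these percentages alone argue against it as their source. The 158 genes restricted to control neobladder stood at a median of 0.151% of that level (0.211 and 0.0275% in experimental replicates 1 and 2), at most 9.2%. Their bound was the 511% of CYP1A1, so they added no separate test of this source. They argue against ileal mucosa as more than a small part of the samples. The 5 other targets of the aryl hydrocarbon receptor tested were higher as a set than in native bladder, with a fry p-value of 0.0148, 3 of 5 having both experimental libraries above both bladder libraries (24.8% of all tested genes did, and chance gives 16.7%) and 0 called. These targets were not tested as a set against control neobladder. CYP1A1 was also higher in control neobladder, at 655 CPM, than in native bladder, at 5.79 CPM, so its rise over bladder was not particular to experimental mucosa. A ligand of that receptor reaching the experimental mucosa may be a candidate explanation, and no measurement of one is in the data.

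The third pattern was the difference between the control neobladder libraries, which correlated less than other replicates. Their difference fell with gene span at a Spearman correlation of -0.361, against -0.13 in experimental neobladder, -0.097 in bladder and 0.023 in peritoneum, over 9297 of 9865 genes. The shortest 20% of genes exceeded the longest 20% by 1.25 log2 units, against 0.16, 0.12 and -0.03. A few genes taking most of the counts would shift all others alike, so alone they would not give this. Such a shift cancels in the measure, so its contribution was not excluded. FABP6 stood at 31400 and 158000 CPM on the TMM scale in control replicates 1 and 2. Unscaled, it had 287901 of 10.96 M and 840735 of 11.88 M counts. The 10 most abundant genes took 16.5 and 22.9% of the unscaled counts, so the FABP6 CPM are not parts of these shares. A difference in RNA quality or library preparation that goes with gene span may be a candidate explanation. Transcript length was not examined, and no biological explanation was tested.

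The 11 HOX genes with a mean of 5 CPM or more in any group were read after their values were seen, and 4 are given. HOXA10 stood at 84.5 ± 13 CPM in experimental neobladder, 73.7 ± 6.91 in native bladder, 14.5 ± 6.5 in peritoneum and 0.242 ± 0.188 in control neobladder. HOXC9 stood at 0.0424 ± 0.0599, 1.34 ± 0.53, 22.1 ± 1.54 and 2.2 ± 0.336 CPM in the same order (n = 2 each). HOXA7 stood at 19.2 ± 7.92, 18.3 ± 1.41, 22.2 ± 1.02 and 1.63 ± 0.61 CPM and HOXB7 at 36.3 ± 2.2, 23.7 ± 7.91, 35.2 ± 3.6 and 46.9 ± 32 CPM. FABP6 was counted in the 6 libraries outside control neobladder at 25.9 to 43.6 CPM, or 0.0275 to 0.0462% of the control mean.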
